A study of Mus musculus with 10 samples.

How the data were processed

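Nuclei came from the thoracic and lumbar spinal cord of adult mice, 6 to 12 weeks old and of both sexes, that carried Cre recombinase behind the Chat gene and a Cre-dependent SUN1 protein fused to a green fluorescent protein. Cholinergic nuclei were captured through that tag with the INTACT method (immunopurification of tagged nuclei), and per the labels' protocols the cords of 2 mice were pooled for each replicate. The captured fraction is called IP here, and the unbound flow-through of the same capture step, which is depleted of tagged nuclei, is called FT. RNA was read with a SMART-seq polyA library amplified over 15 cycles in 2 IP and 2 FT libraries, named A and B. Open chromatin was read with Omni-ATAC, in which a transposase inserts adapters into accessible DNA, from 50000 nuclei over 10 cycles in 3 IP and 3 FT libraries, named 1 to 3.

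The RNA table deposited by the authors holds raw read counts for 25870 gene models, in the layout of featureCounts output with the coordinates of each exon. The ATAC table deposited by the authors holds raw counts for 42680 consensus peaks, each 500 bp wide, whose names join the IP and FT peak lists. Trimmomatic 0.33, Subread 1.4.6-p3, MACS2 2.1.0, bedtools, featureCounts, edgeR and limma are named with no role or order, per the submitters' processing notes, as are the builds GRCm38 and mm10, which share coordinates. The aligner's settings, the strand setting of the counting, and whether ATAC reads were shifted for the transposase or stripped of PCR duplicates are not given in the sources used here. A shift of a few bases matters little for counts in 500 bp windows, whereas retained duplicates would inflate counts and narrow their apparent error. The IP and FT peak lists deposited by the authors have the layout of an irreproducible discovery rate (IDR) comparison between a pair of peak sets that are not named with a −log10 p for each peak. In those deposited lists the score column of −log10 IDR begins at 1.30. One peak list exists per group, so peak lists were compared with no replicate check. Every column of sample values was matched to a sample by its name, and 0 columns were left unmatched.

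RNA totals were 11175905 and 9488934 counts in FT A and B and 8939457 and 10461812 counts in IP A and B. ATAC totals were 7522202, 3382119 and 5193405 counts in FT 1 to 3 and 4198820, 2577334 and 3582397 counts in IP 1 to 3, with a median count per tested peak of 33 to 85. Neither library type carries molecular identifiers, so intervals and floors drawn from counts cover counting error only. No pair of libraries of one group had counts within sampling noise of each other: chi-square per degree of freedom was 26.1 for the RNA FT pair, 78.6 for the RNA IP pair and 1.76 to 8.05 for the ATAC pairs.

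Each comparison of IP with FT used edgeR 4.0.16 in R 4.3.3, with its default filter on low counts, TMM scaling and the robust quasi-likelihood F-test on group alone, and the Benjamini-Hochberg adjustment with a call at an adjusted p under 0.05. This left 15521 genes and 42654 peaks. CPM values were taken after TMM scaling, and errors of levels are SDs between libraries. Errors of log2 fold changes are approximate standard errors, the size of the fold change over the square root of its quasi-likelihood F. A fold change against a group with no counts was bounded by 3 counts over that group. Every p in the text is two-sided. DESeq2 1.42.0 and limma 3.58.1 (voom) served as other tests. On the real tables DESeq2 ran on every feature with any count, without the low-count filter of edgeR.

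The design, the gene lists and most alternatives were fixed before the data were examined. The lists cover cholinergic genes, motor neuron identity, alpha, gamma and visceral motor neurons, cholinergic interneurons, neurofilament and axon genes, Hox genes, excitatory and inhibitory interneurons, pan-neuronal genes, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells, mural cells and fibroblasts, ependymal cells, Schwann cells, motor neuron disease genes, acetylcholine and neuromuscular signalling, glutamate receptors, GABA-A and glycine receptors, voltage-gated calcium and sodium channels, potassium channels, immediate early genes, sex-linked genes and the mitochondrial genome. Each list with enough tested members was tested with limma's camera at a preset correlation of 0.01 on logCPM with a prior count of 2, adjusted over 27 lists. The members were also counted past the threshold when adjusted over the list alone. Camera with an estimated correlation and fry, a rotation test of the list itself, served as alternatives. The genes to name were to be the 12 with the largest and the 12 with the most negative fold change among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted models. Chat, Slc18a3 and Sun1, and up to 4 members of each list with the smallest adjusted p, were to be named as well, and some of the genes so chosen are not reported here. For ATAC, the 8 largest and 8 most negative called peaks with a mean of at least 2 CPM were named, with the peak of smallest p within 100 kb of each cholinergic and motor neuron identity gene. As edgeR called 0 genes, the genes called with the replicate block are described instead, a choice made after their values were seen.

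Peaks were annotated from the exon coordinates of the count table. A gene model was taken to span from its lowest to its highest exon position. Models with exons at distant sites thus span too widely and can inflate the intron class. A peak within 1 kb of the 5′ end of a gene model counted as promoter-proximal and the rest as distal, and 26.8% of the peaks were promoter-proximal, against 2.57% after a shift of all peaks by 1 Mb. The distal share of called and uncalled peaks was compared with Fisher's exact test. Distal peaks were assigned to the nearest 5′ end within 100 kb. As the planned link between called genes and called peaks had no called gene to work on in the unblocked fit, the RNA fold changes of genes with only higher or only lower distal peaks were compared with those of genes with no called peak instead. That test shuffled gene labels 100000 times within classes of peak number, and 2000 times under the alternatives. The share of called peaks per gene list was tested with Fisher's exact test on all peaks within 100 kb of their nearest 5′ end, promoter-proximal ones included. Both were added after the data were seen. Peak lists were compared by an overlap of at least 1 bp. Peaks and genes are not independent replicates in these tests.

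The flow-through was collected in the capture step of one preparation, so a letter or number was taken to pair IP with FT. The labels do not say in words that a letter or number marks one preparation. Deviations from the group means correlated at 0.322 between RNA libraries of one letter, across genes. Between ATAC libraries of one number the values were 0.123, 0.0917 and −0.0114, across peaks. Between IP and FT libraries of different numbers they ran from −0.186 to 0.126, so the ATAC values do not show pairing by number. A fit with the letter or number as a replicate block was an alternative. For RNA the blocked fit leaves 1 residual degree of freedom, against 2 without the block. Its p-values rest largely on variance shared over genes, with a median prior of 4.69 degrees of freedom. Of 388 named or listed genes, 82 share exon positions with another gene model. Since the strand setting is not given, reads of such a gene and its partner could be mixed.

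Each computation was tested on simulated tables with known changes. In the simulated RNA comparison, edgeR ran on 15057 genes and recovered 57.7% of the 4-fold and 85.3% of the 16-fold changes with 5 false calls, against 9 with the replicate block. DESeq2 ran on 15521 simulated genes and recovered 65.0% and 87.0% with 30 false calls. In the simulated ATAC comparison edgeR ran on 42586 peaks and recovered 76.0% of the 2-fold and 100% of the 4-fold changes with 6 false calls. Simulated features scattered around the fitted mean trend alone and had no dispersion of their own, so these rates need not hold for the real tables. Camera found the raised list of 20 genes in 100 of 100 simulated tables of 15521 genes and called an unchanged list in 1. Genes were simulated independently, so this check cannot test the preset correlation between the genes of a list. Alternatives covered the test, the scaling, the low-count filter, the block, the threshold, each library left out, a gene-length offset, promoter windows, link distances and overlap rules. Motif occurrence and a GC-content offset need a genome sequence and were not run.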

Results

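Nuclear RNA and open chromatin were profiled in cholinergic nuclei immunopurified from mouse spinal cord (IP) and in the flow-through left by the same capture (FT). Cholinergic cells of the spinal cord include the motor neurons that drive muscle, the autonomic motor neurons of the thoracic cord and local interneurons. The RNA set had 2 IP and 2 FT libraries of 8939457 to 11175905 counts. The ATAC set had 3 IP and 3 FT libraries of 2577334 to 7522202 counts in peaks. Across genes, log CPM correlated at 0.972 between the FT libraries, at 0.858 between the IP libraries and at 0.866 to 0.909 between IP and FT, so the IP pair was no more alike than IP and FT. Across peaks, the ATAC correlations were 0.967 to 0.976 within FT, 0.914 to 0.945 within IP and 0.628 to 0.802 between IP and FT.

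The first question was which transcripts set cholinergic nuclei apart. Chat, which encodes the enzyme that makes acetylcholine and drives the tag, stood at 45.1 ± 7.62 CPM in IP and 2.14 ± 0.201 CPM in FT (SD, n = 2 per group), a log2 fold change of 4.39 ± 0.41. Slc5a7, the high-affinity choline transporter, stood at 478 ± 0.430 CPM against 31.6 ± 1.22 CPM, a log2 fold change of 3.92 ± 0.28. Slc10a4, a transporter of cholinergic synaptic vesicles, had a log2 fold change of 3.44 ± 0.55. These 3 of the 6 cholinergic genes rose when adjusted over the list alone (edgeR adjusted p = 1.58e-04, 7.93e-05 and 0.00199). Slc18a3, the vesicular acetylcholine transporter, did not pass at 2.32 ± 1.1 (adjusted p over the list alone 0.123). It stood at 345 CPM in IP A but 34.4 CPM in IP B, against 56.6 and 19.2 CPM in FT A and B. With the replicate letter as a block Slc18a3 rose over the list alone (adjusted p = 0.0119) and Ache fell (0.0441). The Slc18a3 gene lies inside the span of Chat on chromosome 14 (Slc18a3 at 32462438 to 32464850, Chat at 32408203 to 32465909, GRCm38, both on the minus strand), so unspliced Chat RNA could add to its count. Sun1, whose mouse form is part of the tag, stood at 126 ± 8.64 CPM in IP and 124 ± 8.0 CPM in FT.

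Of 14 motor neuron identity genes, 14 had a positive fold change and 11 rose when adjusted over the list alone. They were led by Prph, the peripherin filament of neurons that project to the periphery (1312 ± 441 CPM against 58.6 ± 13.7 CPM, log2 fold change 4.48 ± 0.43), and by the LIM homeodomain factors Isl2 (4.49 ± 0.47), Isl1 (4.12 ± 0.53) and Lhx4 (3.82 ± 0.53). Of 12 neurofilament and axon genes, 9 had a positive fold change, and Sncg, the gamma-synuclein gene, rose over the list alone with a log2 fold change of 2.78 ± 0.31. Stmn2 (1.19 ± 0.33), Stmn4 (−0.83 ± 0.29) and Uchl1 (1.16 ± 0.45) did not pass, but with the block 8 genes of that list rose and 1 fell over the list alone. Camera placed cholinergic genes (adjusted p = 5.47e-04), motor neuron identity (6.95e-10) and neurofilament and axon genes (0.0239) above the other genes. With an estimated correlation all 3 had an adjusted p of 0.405. The neurofilament and axon list also lost its call without FT B (adjusted p = 0.0664) and without IP A (0.245).

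Among 12 alpha motor neuron genes, the fast motor neuron genes Chodl (3.35 ± 0.58) and Mmp9 (2.37 ± 0.52) and the peptide receptor gene Vipr2 (3.19 ± 0.57) rose, and the synaptic vesicle gene Sv2a fell by 1.06 on the log2 scale, when adjusted over the list alone. With the block 6 alpha genes rose and 2 fell. None of 12 gamma motor neuron genes passed, with Plch1 at 1.47 ± 0.43, Wnt7a at −1.39 ± 0.50, Nrp2 at 0.89 ± 0.34 and Lypd6 at 1.44 ± 0.58. Of 8 visceral motor neuron genes tested, Slit3, an axon guidance ligand, rose (4.66 ± 0.37), while the peptide genes Sst and Nts fell by 1.74 and 0.88 over the list alone. Mme, at 0.84 ± 0.29, did not pass. Of 6 cholinergic interneuron genes tested, 1 rose and Mpped2 fell by 1.48 over the list alone, while Reln (−1.30 ± 0.69) did not pass. With the block 1 rose and 2 fell. Camera called none of these 4 lists (adjusted p = 0.172, 0.245, 0.816 and 0.664 for alpha, gamma, visceral and interneuron genes), although the alpha list passed without FT A (0.0123). The visceral list had a median log2 fold change of −0.04 with a positive mean of 0.29 and a camera direction of up. The interneuron list had a median of −0.99 with a mean of 0.01 and a camera direction of down.

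**Figure D1:**
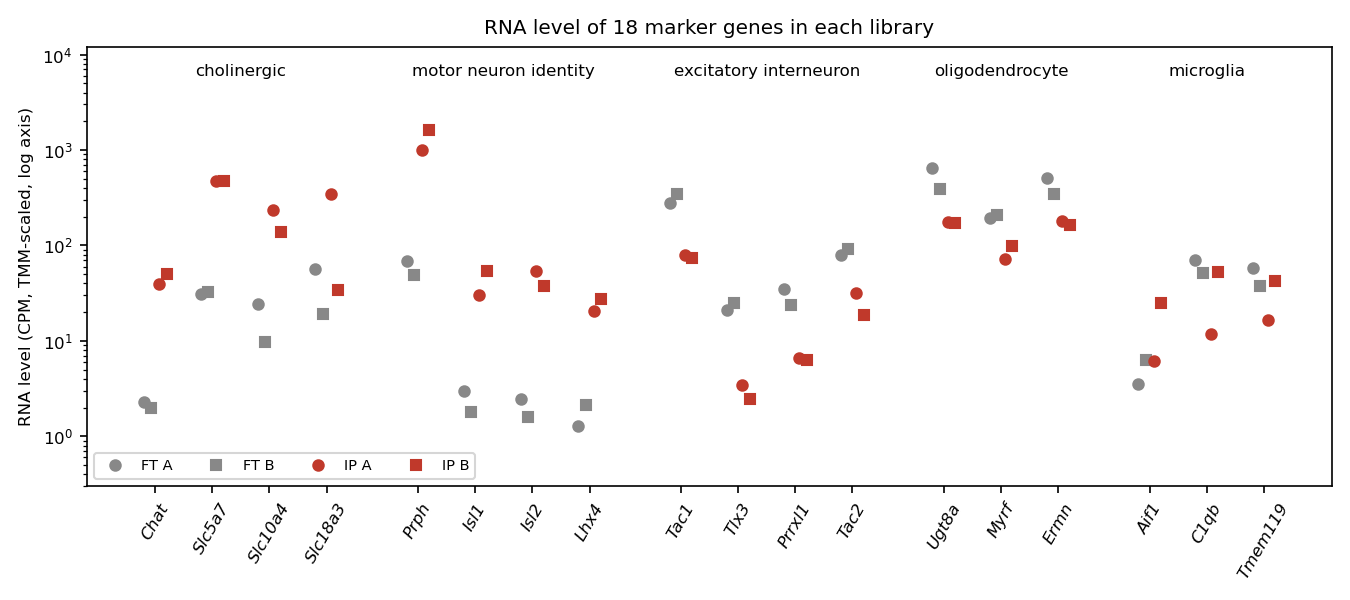
RNA level in CPM (TMM-scaled, log axis) of 18 genes in each of the 4 RNA libraries, with FT in grey, IP in red, preparation A as circles and preparation B as squares. Chat stood near 2 CPM in both FT libraries and at 39.7 and 50.5 CPM in the IP libraries, while microglial genes such as C1qb differed between IP A (11.7 CPM) and IP B (52.4 CPM).

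Of 14 excitatory interneuron genes tested, 13 were negative and 8 fell when adjusted over the list alone, led by Tac1, the substance P precursor (76.2 ± 3.84 CPM against 309.7 ± 48.3 CPM, log2 fold change −2.02 ± 0.27), the dorsal horn factors Tlx3 (−2.97 ± 0.46) and Prrxl1 (−2.20 ± 0.41), and Tac2, the neurokinin B gene (−1.75 ± 0.36). Slc17a8, a vesicular glutamate transporter gene, had 0 counts in both IP libraries and 1.85 ± 0.808 CPM in FT, and was at least 12.1-fold lower in IP when IP is set to 3 counts over the group. The list median was −1.60 both as fitted and with Slc17a8 at that bound. With the block 7 genes fell, without Slc17a8. Of 18 inhibitory interneuron genes, 15 were negative and 4 fell over the list alone, namely Npy (−1.82 ± 0.35), the vesicular GABA transporter gene Slc32a1 (−1.24 ± 0.30), the factor Lhx1 (−2.31 ± 0.56) and the dynorphin precursor Pdyn (−2.87 ± 0.75). Camera placed the excitatory (adjusted p = 9.36e-07) and inhibitory (4.87e-05) lists below the other genes, and both had an adjusted p of 0.405 with an estimated correlation.

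All 20 oligodendrocyte genes had negative fold changes, and 7 fell over the list alone, among them the myelin lipid synthase gene Ugt8a (−1.56 ± 0.34), the myelin regulator Myrf (−1.22 ± 0.28) and Ermn (−1.32 ± 0.31). Of 11 endothelial genes tested, 11 were negative and Ly6c1 fell over the list alone (−2.83 ± 0.48), while Flt1 (−2.07 ± 0.58), Slco1a4 (−1.46 ± 0.42) and Slc2a1 (−1.24 ± 0.40) did not pass. Of 12 mural and fibroblast genes tested, 10 were negative, and Vtn (−2.67 ± 0.39) and Rgs5 (−2.79 ± 0.57) fell over the list alone. Lum, with 0 IP counts, was at least 9.54-fold lower, Myh11 did not pass at 3.07 ± 1.27, and the list median was −1.15 both as fitted and with Lum at its bound. Of 17 astrocyte genes, 14 were negative and 0 passed over the list alone, with Ntsr2 at −1.0 ± 0.38, Slc1a3 at −0.89 ± 0.37, Slc7a10 at −0.83 ± 0.38 and Gpc5 at −0.85 ± 0.43. With the block 15 oligodendrocyte, 4 endothelial and 8 astrocyte genes fell over the list alone. Camera placed the oligodendrocyte (adjusted p = 9.36e-07), endothelial (3.97e-05), mural and fibroblast (0.00279) and astrocyte (0.0389) lists below the other genes. With an estimated correlation their adjusted p was 0.405, 0.405, 0.408 and 0.718. The astrocyte call was also lost without FT A (adjusted p = 0.367), IP A (0.0651) or IP B (0.208) and with no low-count filter (0.0872).

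The oligodendrocyte precursor and microglial lists were not called by camera. Of 10 precursor genes, C1ql1 fell by 1.78 and Tnr, a matrix gene, rose (1.17 ± 0.27) over the list alone, while Lhfpl3 (−0.79 ± 0.27) and Sox6 (−1.33 ± 0.65) did not pass. With the block 1 precursor gene rose and 3 fell. Camera gave an adjusted p of 0.188 and fry 0.0288. The 18 microglial genes differed between the IP libraries: 17 of the 17 with at least 5 CPM were higher in IP B than in IP A, by a median of 2.13 on the log2 scale. The 7 tested genes of the mitochondrial genome were higher in IP B too, by a median of 1.73. Against FT, for microglial genes, camera gave an adjusted p of 0.534 in the downward direction with both IP libraries, 0.00214 upward without IP A, and 2.08e-05 downward without IP B. Aif1 (1.66 ± 0.79), C1qb (−0.92 ± 0.69) and Tmem119 (−0.68 ± 0.52) did not pass. The microglial list median was −0.02 with a positive mean of 0.16.

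**Figure D2:**
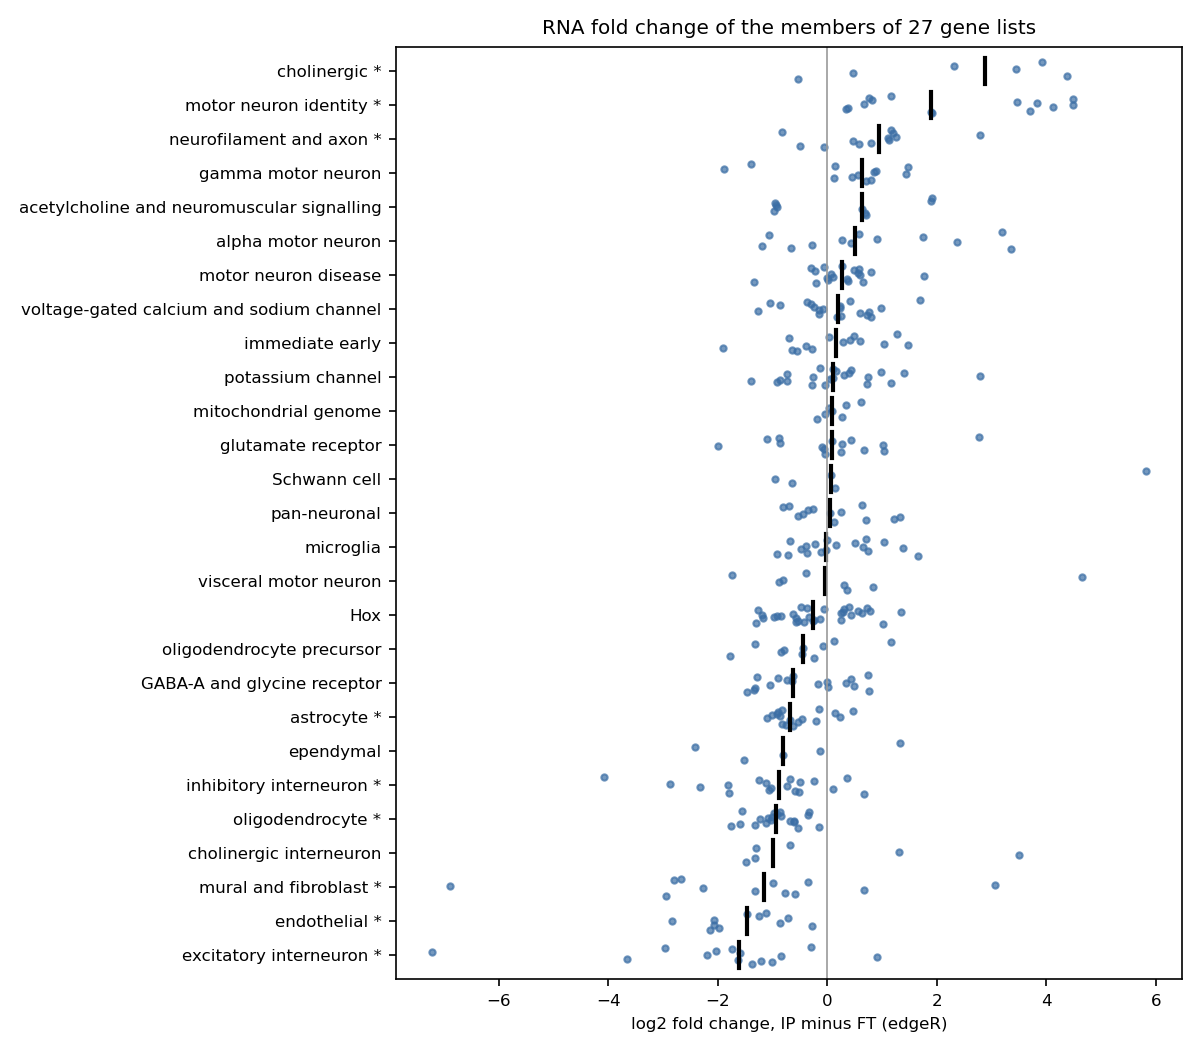
Log2 fold change of RNA, IP minus FT, for the tested members of 27 gene lists, with 1 point per gene and a black bar at the list median. Asterisks mark the 9 lists past camera's adjusted p at the preset correlation, from cholinergic genes (median 2.88) to excitatory interneuron genes (median −1.60), and fitted values of genes with 0 counts in IP, such as Slc17a8, are no bounds.

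Over all 15521 genes, edgeR called 0 genes, with 1801 genes at an unadjusted p under 0.05 (825 higher and 976 lower in IP) and a smallest adjusted p of 0.109. DESeq2 called 428 genes, but it ran on 20053 genes without the low-count filter, and edgeR called 53 on that set. On the filtered genes limma-voom called 0. In the simulated RNA comparison, whose genes had no dispersion of their own, DESeq2 made 30 false calls and edgeR 5. Those rates need not hold for the real table and do not show which test to trust there. With the replicate letter as a block, which leaves 1 residual degree of freedom, edgeR called 31 genes, 27 higher and 4 lower in IP. These were singled out after their values were seen. Besides Slc5a7, Chat, Slc10a4, Isl2, Prph, Calcb, Chodl, Slit3, Sncg and members of the receptor and channel lists, the higher genes were led by the matrix gene Postn (log2 fold change in the blocked fit 5.28 ± 0.47, adjusted p = 0.0338), the predicted model Gm7694 (4.75 ± 0.29, adjusted p = 0.0175) and the scaffold gene Ahnak2 (4.55 ± 0.28, adjusted p = 0.0175). They also included the annexin genes Anxa4 and Anxa2, the stem cell factor gene Kitl and the peptide precursor gene Cartpt. The 4 lower genes were F2rl2, a thrombin receptor family member (−3.16 ± 0.30, adjusted p = 0.0365), Slc30a3, the zinc transporter of synaptic vesicles (−2.72 ± 0.25, adjusted p = 0.0365), the protocadherin gene Pcdh8 (−2.55 ± 0.26, adjusted p = 0.0466) and Hbb-bs, a beta-globin gene with a near-identical copy that could share its reads (−2.04 ± 0.21, adjusted p = 0.0466). Without either IP library edgeR called 3940 genes (IP A left out) or 3918 genes (IP B left out), with the lone IP library assumed to vary like the FT pair. It called 13 genes without FT A, 14 without FT B and 53 with no low-count filter.

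The second question was where chromatin accessibility differed between the same populations. Of 42654 peaks, 11024 were higher and 11306 lower in IP (edgeR adjusted p under 0.05). Mitochondrial peaks took 3.03% to 6.79% of the counts in IP and 2.32% to 3.56% in FT, and without mitochondrial and Y peaks 11438 peaks were higher and 10761 lower. The peak of smallest p near Chat lay at chromosome 14, 32468570 to 32469069, 2.91 kb upstream of the 5′ end of Chat and in an intron of the model Gm2990. It held 40.8 ± 11.2 CPM in IP and 1.16 ± 0.223 CPM in FT (SD, n = 3 per group), a log2 fold change of 5.13 ± 0.29 (edgeR adjusted p = 3.07e-13). Among the IP libraries it stood lowest in IP 1 (28.0 CPM, against 45.4 in IP 2 and 48.8 in IP 3), the library with the highest mean correlation with FT (0.791, against 0.668 and 0.641). Of the other 3 peaks within 100 kb of Chat, those at 32472938 (log2 fold change 0.35 ± 0.17) and 32513191 (0.08 ± 0.15) did not pass, and that at 32535403 fell (−1.16 ± 0.25, edgeR adjusted p = 2.90e-04). The falling peak lies nearer the 5′ end of Prrxl1, 63.8 kb upstream of it, than that of Chat.

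**Figure D3:**
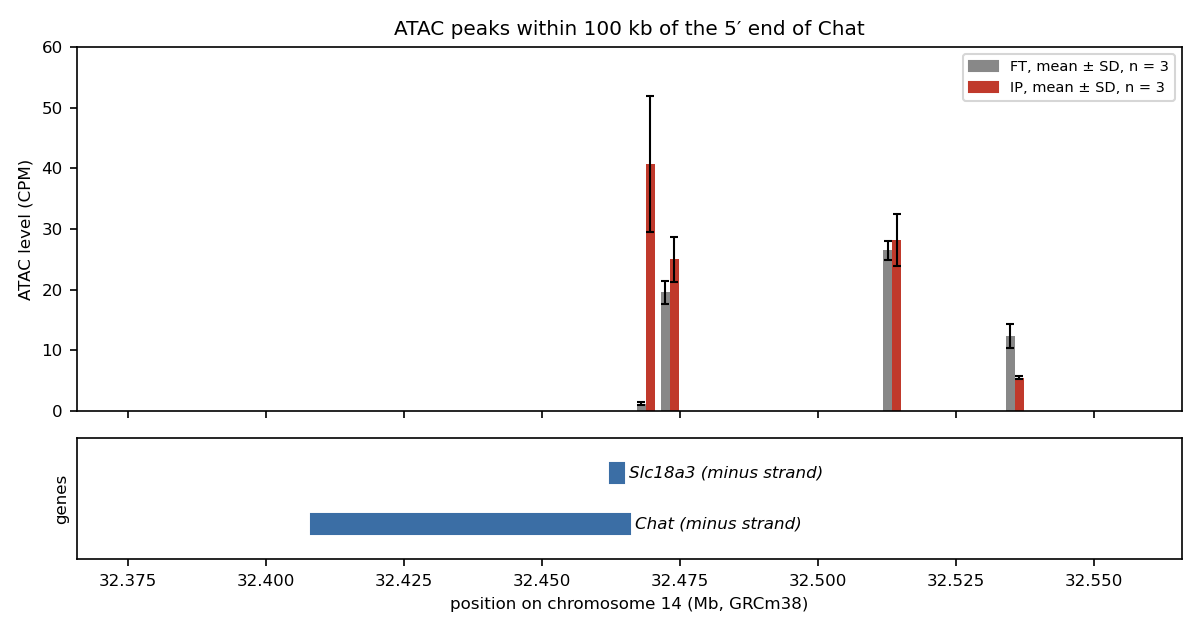
Mean ATAC level in CPM with SD of the 4 tested peaks within 100 kb of the 5′ end of Chat, in FT (grey) and IP (red), above the spans of Chat and Slc18a3. Bars are drawn wider than the 500 bp peaks and to the left (FT) and right (IP) of each peak centre, and the peak nearest the start of Chat rose from 1.16 to 40.8 CPM.

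The peak of smallest p within 100 kb was higher in IP for 15 of the 20 cholinergic and motor neuron identity genes, lower for 3 and uncalled for 2, where Chat and Slc18a3 share 1 peak. Over the 15245 tested genes with a peak within 100 kb it was higher for 47.3%, lower for 45.7% and uncalled for 6.98%, a count added after the data were seen, and the difference was not tested. Promoter-proximal peaks rose at Slc10a4 (chromosome 5, 73006605 to 73007104, log2 fold change 3.59 ± 0.28, edgeR adjusted p = 4.52e-11) and Isl1 (chromosome 13, 116309475 to 116309974, 3.37 ± 0.29, adjusted p = 2.34e-10). Intergenic peaks rose upstream of Mnx1, the homeobox gene also known as Hb9 (chromosome 5, 29508728 to 29509227, 5.21 ± 0.66, adjusted p = 4.28e-07), Lhx4 (chromosome 1, 155751626 to 155752125, 4.41 ± 0.46, adjusted p = 6.32e-09) and Prph (chromosome 15, 99044786 to 99045285, 3.78 ± 0.48, adjusted p = 2.33e-07). Of the 11 peaks near Prph, 2 rose and 3 fell. Peaks inside Tns1 (chromosome 1, 74008451 to 74008950, intron, 3.14 ± 0.27, adjusted p = 4.05e-10) and in the intergenic DNA beyond Slc5a7 (chromosome 17, 54239397 to 54239896, 3.44 ± 0.30, adjusted p = 3.29e-10) rose too. The peaks of smallest p near Isl2 (−0.28 ± 0.13), whose RNA rose, and Gfra1 (0.49 ± 0.22), whose RNA did not pass (0.38 ± 0.35), did not pass. Near Ache that peak fell (−0.53 ± 0.18), with 0 higher and 3 lower of 8 peaks, and the RNA did not pass (−0.53 ± 0.31). Near Pcyt1b it fell (−1.75 ± 0.27), with 2 higher and 1 lower of 4 peaks, and the RNA did not pass (0.47 ± 0.27). Near Calcb, whose RNA rose (3.71 ± 0.64), it fell (−1.88 ± 0.17, in an intron of Insc), while 5 of 9 peaks were higher and 2 lower. With the number as a block the Isl2 peak passed at an adjusted p of 0.0496 in the same direction.

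Among the 8 peaks with the largest fitted increase, 3 were intergenic, 5 were labelled intronic, and 8 of 8 were distal. The intron label of the peak at chromosome 4, 9206372 to 9206871, is doubtful. Its host model Ccl27a also overlaps Gem at 11704457 to 11714752, and the peak lies 62.7 kb upstream of Clvs1. A peak at chromosome 19, 16813214 to 16813713, 32.6 kb upstream of Vps13a, had 0 counts in 3 of 3 FT libraries and 8.77 ± 3.30 CPM in IP, at least 47.1-fold higher when FT is set to 3 counts over the group. A peak at chromosome 4, 94223408 to 94223907, in an intron of Gm12648, likewise had 0 FT counts and was at least 45.2-fold higher. The next, at chromosome 6, 4022666 to 4023165, had a log2 fold change of 6.20 ± 0.46 and lay 19.0 kb from the 5′ end of Gng11. The largest decreases were smaller. They were led by a peak in an intron of Myl1 on chromosome 1, 66932527 to 66933026 (−3.01 ± 0.41, adjusted p = 5.45e-07), and included a peak in an intron of Sox2ot, the transcript that spans the stem cell gene Sox2 (chromosome 3, 34119591 to 34120090, −2.77 ± 0.38, adjusted p = 5.75e-07).

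The changed peaks lay away from promoters more often than the others. Distal peaks made up 84.4% of the 11024 higher peaks, 72.1% of the 11306 lower peaks and 67.8% of the 20324 uncalled peaks. Against uncalled peaks the odds ratios were 2.56 for higher peaks (Fisher's exact test, p = 6.94e-234) and 1.22 for lower peaks (p = 4.49e-15), and higher exceeded lower peaks with an odds ratio of 2.09 (p = 7.74e-111). By these labels introns held 4497 of the higher peaks and intergenic DNA 4207. Some intron labels may stem from gene models that span too widely.

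Peaks, promoter-proximal ones included, were also counted by the list of the gene with the nearest 5′ end within 100 kb. Of 98 peaks at oligodendrocyte genes, 73 (74.5%) were lower in IP, against 26.1% of all 36928 assigned peaks (Fisher's exact test, adjusted p = 8.64e-22). A raised share of higher peaks, against 24.7% of all assigned peaks, was found for alpha motor neuron genes (14 of 26, adjusted p = 0.0242), motor neuron identity (12 of 23, 0.0304), pan-neuronal genes (16 of 33, 0.0266), glutamate receptors (19 of 41, 0.0266), calcium and sodium channels (17 of 37, 0.0308) and potassium channels (20 of 45, 0.0285). Cholinergic genes had 7 of 13 higher peaks and did not pass (0.0943). Inhibitory interneuron genes had 7 higher and 2 lower of 22 peaks, and excitatory interneuron genes 11 higher and 10 lower of 31, none past the test (adjusted p = 0.636, 0.262, 0.375 and 0.593 in that order). The number of lists with a raised higher share fell from 6 to 2 with DESeq2, 1 with cyclic loess offsets, 2 without FT 1 or FT 2, 3 without FT 3 and 1 without IP 2 or IP 3, while the oligodendrocyte decrease kept 71.4% to 73.5% lower peaks under all of those settings.

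**Figure D4:**
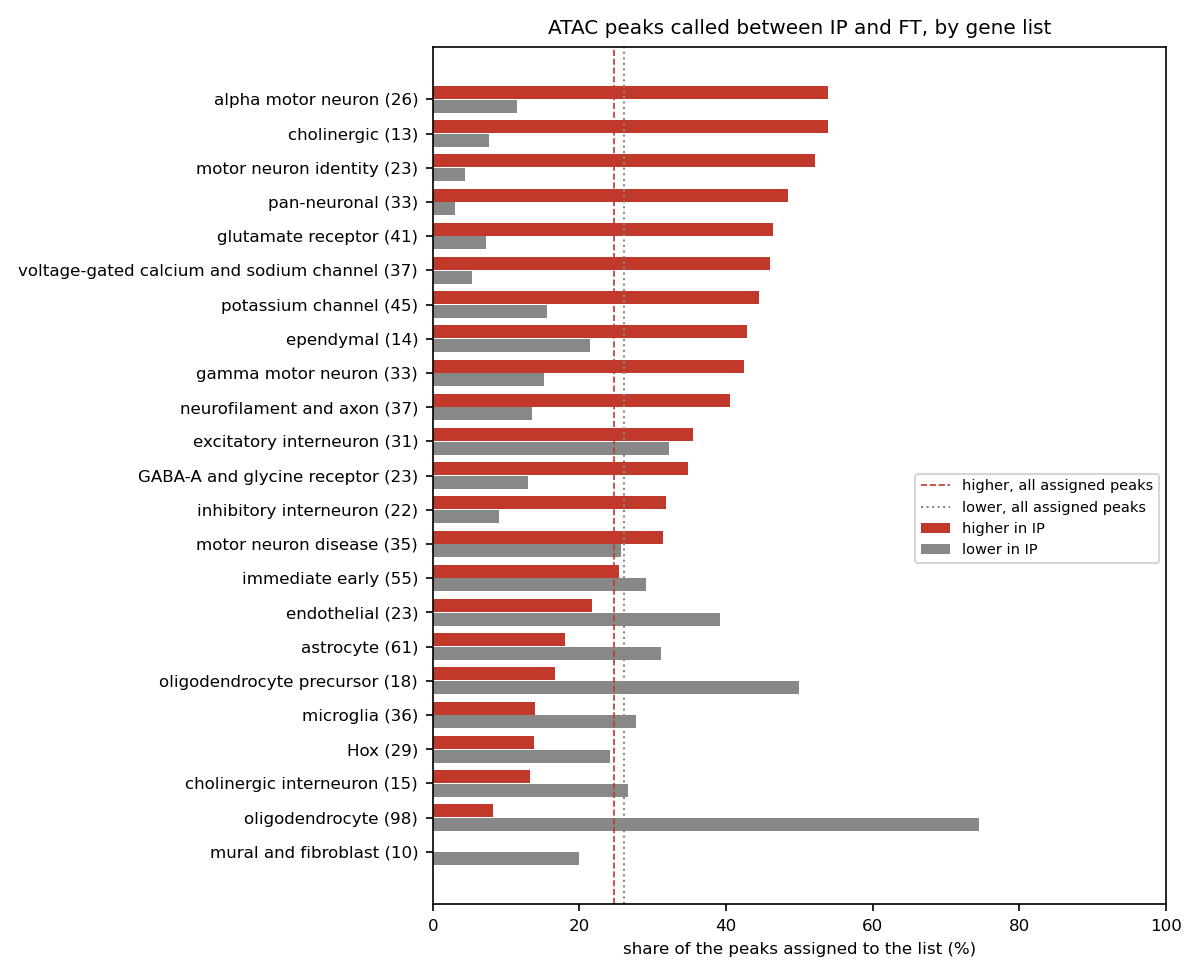
Share of the ATAC peaks assigned to each gene list that were called higher (red) or lower (grey) in IP, in percent, for the lists with at least 10 peaks (number of peaks in brackets), with dashed and dotted lines at the shares over all assigned peaks. The oligodendrocyte list stands apart with 74.5% lower peaks, and motor neuron identity has 52.2% higher peaks.

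The third question was whether RNA and chromatin moved together at single genes. The 2701 genes whose called distal peaks were all higher had a median RNA log2 fold change of 0.10, the 2143 with only lower peaks −0.17 and the 2613 with no called distal peak 0.03. The mean exceeded that of genes with no called peak by 0.18 for genes with only higher peaks (permutation p = 2.00e-05, 100000 shuffles). It differed by −0.13 for genes with only lower peaks (permutation p = 0.00378). In the same permutation test the excess was 0.13 (p = 0.0115) without RNA IP A and 0.37 (p = 5.00e-04, the smallest that 2000 shuffles can give) without RNA IP B. The decrease did not pass that permutation test with the block (−0.08, p = 0.0875), without RNA IP B (−0.01, p = 0.860) or without ATAC IP 1 (−0.06, p = 0.197). Of the genes called higher with the block, 16 had a distal peak, and 13 of those had a distal peak that was higher in IP, against 6.80 by chance within classes of peak number (permutation p = 0.00210). DESeq2 called 204 higher and 224 lower genes, of which 113 and 154 had a distal peak. Of those, 79 higher genes (46.8 by chance) had a higher peak (permutation p = 2.00e-05), and 81 lower genes (62.0 by chance) had a lower peak (p = 9.80e-04).

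The peak lists of the authors, made per group, were compared as sets. The IP list held 22403 peaks and the FT list 37365, and 78.4% of the IP peaks overlapped an FT peak while 47.0% of the FT peaks overlapped an IP peak. This left 4844 peaks in the IP list alone and 19813 in the FT list alone. The FT list has a higher median −log10 p (31.4 against 19.9) and its libraries held more counts together, so the lengths of the lists do not compare the number of open sites.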

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

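The tests of RNA fold change by peak class and of peaks per gene list, the stricter −log10 p of 20 and the fit without mitochondrial and Y peaks were chosen only after the results were seen. The count of called RNA genes, 0 as reported with edgeR, was the least stable value: 428 with DESeq2, 53 with no low-count filter, 31 with the replicate block, 260 with a gene-length offset and the block, and 13 to 3940 with each library left out, highest without IP A; it stayed 0 with limma-voom, other scalings, the mean CPM filter, the gene-length offset alone and stricter thresholds. Fewer libraries with a smaller spread between them account for the many calls when an IP library is left out, since the biological coefficient of variation was 0.213 in the FT pair and 0.594 in the IP pair; for the other settings the cause was not tested. The count of called peaks was 11011 when a fold of at least 2 was also required, which follows from the added condition, and 18180 to 24501 with each library left out. It was 22744 with the replicate block, and the higher share ran from 48.8% to 53.3% over all scalings and tests. The block changed no call of the 27 camera tests, but raised the list members past the test over their list alone from 26 higher and 30 lower to 48 higher and 64 lower, with 58 gained and 2 lost (Slc17a8 and Prx); the cause was not tested. List tests past the threshold fell from 9 to 0 with an estimated correlation and numbered 3 with fry (motor neuron identity, excitatory interneuron and, not among the 9, oligodendrocyte precursor), and were 8 to 9 with each library left out. The microglial list reversed without IP A (adjusted p = 0.00214, upward), against 2.08e-05 to 0.821 over the other libraries left out. Without IP B, mt-Nd6 (−1.08) and mt-Cytb (−0.875) reversed, while without IP A both stayed positive (1.36 and 0.888). Without FT A or FT B they ran from −0.0583 to 1.82 and from −0.115 to 0.739. The reversal follows the IP library kept: the 7 tested mitochondrial genes lay below FT in IP A (median −0.853) and above it in IP B (0.851). Why the IP libraries differ was not tested. Of the IP peaks, 76.3% overlapped FT peaks by at least 50% of each, 91.4% at a −log10 p of at least 20 and 66.4% with equal numbers of top peaks; of the FT peaks, 45.7%, 37.9% and 66.2% did so. The first of these values follow from the stricter overlap rule; the other settings change both the sizes of the lists and the strength of their peaks, and the cause was not tested. Genes with only higher distal peaks had a mean difference in RNA of 0.13 without RNA IP A and 0.373 without RNA IP B, against 0.184; the cause was not tested. Genes with only lower distal peaks had one of −0.0799 with the block and −0.163 to −0.0135 with each library left out. Lists with a raised share of higher peaks numbered 2 with DESeq2, 1 with cyclic loess offsets and 1 to 7 with each library left out, against 6; the cause was not tested. The distal shares kept their order in every window, in the block fit and in each fit with a library left out. Named peaks kept direction and call in 534 of 540 fits. Among the 132 genes that the naming rules chose, 1295 fits stayed on the same side of the threshold, 410 passed it and 2 reversed. A mean filter of 2 CPM removed no peak and tests nothing. The GC-content offset and motif occurrence were not run, and the planned link of called genes with called peaks has no value in the unblocked fit. At these depths a gene with 0 counts in both IP libraries could still hold 0.153 CPM.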

Other observations

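Tests of depth, of mixture with FT nuclei, of carryover, of sampling and of a shared difference between preparations were chosen only after the result was seen, and the count of other splits of the ATAC libraries was planned. Of 15 glutamate receptor genes tested, Grin3b, an NMDA receptor subunit gene, rose (log2 fold change 2.77 ± 0.26, 128 ± 3.89 CPM in IP against 18.7 ± 0.766 CPM in FT, SD, n = 2) and the kainate receptor gene Grik3 fell by 2.00, both with edgeR and adjusted over the list alone, while Grin3a (−0.87 ± 0.30) and Grin1 (−0.86 ± 0.30) did not pass. Grin3b shares exon positions with Tmem259 on the other strand. Of 17 GABA-A and glycine receptor genes, 1 fell over the list alone, and Gabra3 (−1.33 ± 0.31), Glra3 (−1.29 ± 0.40) and Gabra4 (−1.31 ± 0.44) did not pass. Of 22 potassium channel genes, the inward rectifier gene Kcnj14 rose (2.78 ± 0.52) over the list alone, and Kcnc2 (−1.4 ± 0.31), Kcnb2 (1.17 ± 0.30) and Kcnn3 (1.4 ± 0.36) did not pass. None of 20 calcium and sodium channel genes passed, with Scn9a at 1.69 ± 0.33, Cacna2d3 at 0.98 ± 0.29, Scn2b at −0.87 ± 0.31 and Cacna1d at 0.73 ± 0.31. Among 9 acetylcholine and neuromuscular signalling genes tested, Nrg1, the neuregulin gene, rose (1.92 ± 0.36) over the list alone, while Chrnb2 (−0.95 ± 0.30), Chrm2 (0.70 ± 0.41) and Chrna4 (−0.92 ± 0.59) did not pass. Camera called none of these 5 lists (adjusted p = 0.653, 0.188, 0.402, 0.510 and 0.992 in that order), and the last had a median of 0.63 with a camera direction of down. Without IP A the GABA-A and glycine receptor list passed (adjusted p = 0.0266, down). With the replicate block, genes past the test over the list alone numbered 4 higher and 3 lower for glutamate receptors, 2 higher and 4 lower for GABA-A and glycine receptors, 4 higher and 2 lower for potassium channels, and 1 higher and 0 lower for both calcium and sodium channels and acetylcholine and neuromuscular signalling.

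None of 19 motor neuron disease genes passed over the list alone, with Nek1 at 1.77 ± 0.42, Tbk1 at 0.59 ± 0.25, Sod1 at 0.80 ± 0.37 and Optn at 0.59 ± 0.33. None of 31 Hox genes passed, with Hoxa10 at −1.30 ± 0.31, Hoxb7 at −1.20 ± 0.31, Hoxb5 at −0.84 ± 0.27 and Hoxb6 at −0.92 ± 0.35. Of 14 immediate early genes tested, Egr1 fell by 1.91 over the list alone, and Jund (−0.69 ± 0.34), Btg2 (−0.63 ± 0.37) and Jun (0.60 ± 0.41) did not pass. Of 13 pan-neuronal genes, Elavl4 rose (1.23 ± 0.25) over the list alone, and Syt1 (−0.69 ± 0.27) and Syp (−0.81 ± 0.34) did not pass. Of 5 Schwann cell genes tested, Prx, a peripheral myelin gene, rose over the list alone with 6.42 ± 3.41 CPM in IP against 0 and 2 counts in the FT libraries, while Ncmap, Fbln5 and Pmp22 (191 ± 67.2 CPM against 183 ± 48.1 CPM) did not pass. None of 5 ependymal genes tested passed, with Rarres2 at −2.42 ± 1.6. None of 7 mitochondrial genome genes tested passed, with mt-Nd6 at 0.62 ± 0.94 and mt-Cytb at 0.27 ± 0.62. Camera gave adjusted p of 0.188, 0.256, 0.860, 0.992, 0.848, 0.510 and 0.990 for these lists in that order, and the immediate early list had a positive median of 0.16 with a camera direction of down. Too few sex-linked genes were tested for camera. Of these Xist stood at 241 CPM in FT A and 236 CPM in IP A but 777 CPM in FT B and 611 CPM in IP B, and Tsix at −0.92 ± 0.49 did not pass. Reads of the Y genes Ddx3y, Uty, Kdm5d and Eif2s3y, before TMM scaling, were 0.447 and 0.211 CPM in RNA FT A and B. They were 0 and 0.191 CPM in RNA IP A and B. The RNA libraries thus held Xist but next to no reads of these Y genes, and show no sign of male nuclei. In the ATAC libraries Y chromosome reads ran from 142 to 210 CPM, counted over peaks rather than genes. The sex of the mice in each pool is not given in the sources used here. Counts over Y genes and over Y peaks are not on one scale, so whether the RNA and ATAC pools differed in sex make-up stays open. With the block, Nek1 (adjusted p over the list alone 0.00314) and Tsix (0.0152) passed, Prx did not (0.0768), and 3 pan-neuronal genes rose and 2 fell over the list alone. Tsix shares exon positions with Xist on the other strand, so reads of Xist could be counted as Tsix.

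ATAC IP 1 lay closer to FT than the other IP libraries, with a mean correlation of 0.791 with the FT libraries against 0.668 for IP 2 and 0.641 for IP 3. Unequal depth is argued against as the whole cause, since the lead was 0.123 before and 0.109 after all libraries were thinned to one total. A larger share of FT-type nuclei in IP 1 may account for it and stays open. Turning another IP library into IP 1 took an FT share of 0.308 to 0.461 at higher peaks and 0.151 to 0.244 at lower peaks, a gap of 0.187 between the means against a range of 0.154 between reference libraries. Biological differences between the pooled mice were not tested.

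RNA IP A and IP B differed more than FT A and FT B, and 108 of 12509 genes with at least 5 CPM in FT had 0 counts in IP A against 14 in IP B. An equal rise of all other cell types in IP B is argued against. The glial and vascular lists moved apart by 2.95 on the log2 scale, from microglia (2.13 higher in IP B) to endothelial genes (median −0.82). Microglia stood alone, as the medians of the other lists ran from −0.82 to 0.38. The B to A ratio of FT was not subtracted, and an unequal rise of some cell types was not tested. Few RNA molecules from few nuclei may widen the spread of genes of 4 to 16 CPM, where the IP spread relative to FT was 1.48 times that of genes at a log2 CPM of 6 to 8, but in the latter the excess was 1.41 times what such sampling predicts. A difference between preparations A and B that IP and FT share is a candidate explanation for another part: over 9706 genes of at least 16 CPM the B to A log ratios of IP and FT correlated at 0.566, and subtracting the FT ratio lowered the SD of the IP ratio from 0.782 to 0.646. Mitochondrial genome genes were also higher in IP B, in 7 of 7 genes by a median of 1.73, and took 0.0897% of the counts there against 0.0266% in IP A, 0.0717% in FT B and 0.0368% in FT A. The microglial difference, which a change in that cell type could also give, the mitochondrial one and biological differences between the mice stay open.

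Only 1 of the 10 splits of the 6 ATAC libraries into 3 and 3, the real split, called as many as 22330 peaks, and the highest of the other splits called 0. The splits are too few for a share under 0.05. Of the other splits, 3 also part each numbered pair, and they called 0 peaks. Every other split mixes IP and FT libraries within both groups, which widens the spread within groups. The 0 calls of those splits thus do not show how many peaks would be called without a difference.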
